A study of Homo sapiens with 9 samples.

How the data were processed

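RNA sequencing libraries of H9-derived definitive endoderm were made from total RNA and sequenced on an Illumina instrument, per the labels. The deposited table holds raw read counts per Ensembl gene, with 1 column per library and no pooling of replicates. Per the submitters' processing notes, the tools FastQC, Trimmomatic, HISAT2, SAMtools and HTSeq and the build hg38 were used, without versions, roles or order. The annotation release, the strand setting and the rule by which genes were kept in the table are not given in the sources used here. The unit was checked on the values: all counts are whole numbers and the columns sum to 11854173 to 37519729. The table lists 26240 genes, of which 264 have 0 counts in all 9 libraries. Symbols were found for 26177 genes and coordinates, from GENCODE release 29 on GRCh38, for 25209. Of the 19951 protein-coding genes of that release, 3774 have no row, so genes without a row were not analysed here.

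Genotypes and replicate numbers were taken from the labels. The 3 comparisons were homozygous against wild type, heterozygous against wild type and homozygous against heterozygous. In R 4.3.3 with edgeR 4.0.16, genes were filtered with filterByExpr by genotype, which left 16837 genes and removed 9403. Counts were scaled with TMM factors (0.973 to 1.01) and fitted with the quasi-likelihood model on all 9 libraries in 1 fit, with genotype as the only factor. The common biological coefficient of variation was 0.121. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method, and a gene was called below 0.05. The SE of a log2 fold change is its size divided by the square root of F. Levels in CPM are the deposited counts scaled to the TMM-adjusted library size.

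The 28 gene lists, like the rule for named genes and the alternatives given first in the last paragraph, were fixed before the data were examined. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, where at least 5 members were tested. This left 27 lists. Camera with an estimated correlation called 0 lists in each comparison, the lowest adjusted p being 0.326, 0.654 and 0.138. Fry, which asks whether a list's genes move on balance in 1 direction, called 8, 2 and 5 lists, and its mixed test, which asks for change in either direction, called 23, 24 and 23. The named genes are CHD7, then in each comparison with wild type the 8 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher genotype and no overlap between the libraries, and 5 and 5 between the mutants, leaving out some symbol classes such as ribosomal and uncharacterised genes. They also include 13 endoderm and pluripotency genes and up to 4 called members of each list, 99 genes in all. YPEL3 and NECTIN3 were added after the values were seen, as neighbours of named genes. Some of the named genes are not reported here.

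Where a genotype had 0 counts of a gene, the fold is given as a lower limit with a floor of 3 counts over the genotype. Floors and 95% intervals of counts cover counting error only, since reads without molecular identifiers are not independent molecules. Homozygous replicate 1, with 11854173 counts, was the shallowest library. Replicates of a genotype were compared by a chi-square of their counts over genes, and the values per degree of freedom lay between 2.70 and 34.3. No pair was therefore treated as 1 library. The value of 2.70 belonged to wild-type replicates 2 and 3, which were closer to each other than any other pair, the next lowest value being 8.055. Such values do not exclude that 2 libraries came from 1 culture. The test was run on simulated counts, 1 set per comparison, with 200 changed genes picked among those with a mean of at least 1 CPM. Counts were drawn independently per gene from the negative binomial model with the fitted dispersions. The rates therefore hold under that model and do not cover changes in genes at lower levels. For homozygous against wild type (16550 genes) it recovered 48.5% of 1.5-fold, 92.4% of 2-fold and 97.0% of 4-fold changes, with 4.82% of calls false. For heterozygous against wild type (16580 genes) these were 50.0%, 86.4% and 98.5% with 6.59% false, and for homozygous against heterozygous (16580 genes) 58.8%, 84.9% and 98.5% with 5.29% false. The simulated sets with a known order of the genotypes were drawn from negative binomial counts with the fitted dispersions and the mean levels of wild-type and homozygous cells. Those observed means were taken as true, noise included.

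The alternatives fixed in this way were size factors by relative log expression, upper quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the 6 libraries of a comparison alone, the replicate number as a block, a test against a 1.5-fold change (glmTreat), both other list tests, and leaving out each library. Thinning all libraries to the total of the shallowest, the pluripotency list as a covariate, leaving out the replicates numbered 3 and removing the GC trend of each library (98.2% of genes had a GC value) were added after the data were seen. Figures were drawn with matplotlib 3.10.9.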

Results

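Gene expression was measured by RNA sequencing in definitive endoderm derived from H9 cells, an established human embryonic stem cell line. CRISPR/Cas9 had been used to delete CHD7, which encodes an ATP-dependent chromatin remodeller whose mutation underlies most cases of CHARGE syndrome. The study set out to compare gene expression among endoderm cells with both, 1 or no intact copies of the gene. The 9 libraries fell into 3 genotypes, wild type, heterozygous and homozygous mutant, with 3 libraries in each. The total count per library was 37519729, 31128215 and 24781297 in wild-type replicates 1, 2 and 3, 30581464, 27083663 and 23488722 in the heterozygous replicates, and 11854173, 29849352 and 19911079 in the homozygous replicates. The labels name no separate cultures, days or clones, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as counts scaled to library size (CPM), as the mean ± SD of 3 libraries, and log2 fold changes with their standard error (SE) and the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test.

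The CHD7 transcript followed the labelled genotypes in every library. CHD7 (ENSG00000171316) lies on chromosome 8 from 60678778 to 60868028 on the plus strand of GRCh38. Its level was 193 ± 3.29 CPM in wild-type cells (SD, n = 3), 123 CPM in heterozygous cells (110.4, 130.5 and 129.2 CPM in replicates 1, 2 and 3) and 51.5 ± 7.41 CPM in homozygous cells (SD, n = 3). The log2 fold change was -1.91 (SE 0.11, adjusted p = 5.25e-07) in homozygous against wild-type cells and -0.65 (SE 0.10, adjusted p = 0.00579) in heterozygous against wild-type cells. Homozygous cells also lay below heterozygous cells, by a log2 fold change of -1.26 (SE 0.11, adjusted p = 3.53e-05). The heterozygous fall was no longer called when tested against a 1.5-fold change (adjusted p = 1). The labels do not give the deleted interval, and counts summed over the gene do not show whether the remaining transcript carries the deletion.

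**Figure D1:**
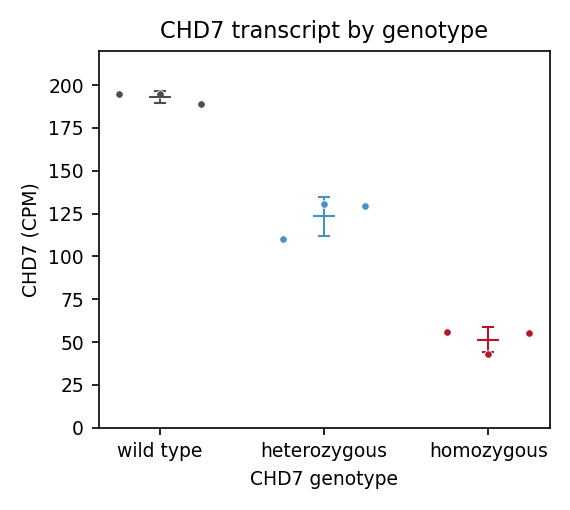
CHD7 level in CPM (vertical axis, from 0) by genotype (horizontal axis), with 1 point per library, horizontal bars for the means and error bars for the SD of 3 libraries. The 3 genotypes do not overlap, with means of 193, 123 and 51.5 CPM.

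In homozygous cells several core endoderm transcripts remained abundant, while a subset of endoderm regulators was lower. FOXA1, a pioneer transcription factor of endoderm on chromosome 14 (37589984 to 37596059, minus strand), stood at 20.6 ± 4.96 CPM in wild-type and 2.68 ± 0.378 CPM in homozygous cells, a log2 fold change of -2.92 (SE 0.20, adjusted p = 2.16e-06). Its paralog FOXA2 went from 156 ± 14.6 to 107 ± 6.95 CPM (log2 fold change -0.55, SE 0.09, adjusted p = 0.00302). CER1, a secreted Nodal and BMP antagonist, went from 7245 ± 399 to 4629.9 ± 596 CPM (-0.65, SE 0.11, adjusted p = 0.00257). MIXL1, a homeobox gene of the mesendoderm, also fell (-0.54, SE 0.09, adjusted p = 0.00192), as did HHEX, a homeobox gene of the anterior endoderm (-0.44, SE 0.09, adjusted p = 0.0124). FRZB, a secreted Wnt inhibitor, rose from 42.6 ± 3.12 to 79.0 ± 12.8 CPM (0.89, SE 0.11, adjusted p = 0.000291). The endoderm transcription factor SOX17 stood at 717 ± 15.0 CPM in wild-type and 629.6 ± 40.9 CPM in homozygous cells and did not pass the test (adjusted p = 0.197). The chemokine receptor CXCR4 (adjusted p = 0.594), GATA4 (0.671), GATA6 (0.590), EOMES (0.0811) and GSC (0.487) did not pass it either. Of the 25 tested members of the definitive endoderm list, 3 rose, 4 fell and 18 were not called. Adjusted over the list alone, 3 rose and 5 fell, and the list itself was not called (camera, adjusted p = 0.0847). The call of HHEX was lost without wild-type replicate 2 (adjusted p = 0.0617), and tested against a 1.5-fold change FOXA2, CER1, MIXL1, HHEX and FRZB were no longer called.

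The pluripotency factors POU5F1, NANOG and SOX2 varied widely between libraries of a genotype. POU5F1, a core pluripotency factor whose reads can be shared with its retrocopies, stood at 69.6 ± 22.3 CPM in wild-type, 159 ± 39.4 CPM in heterozygous and 90.0 ± 49.1 CPM in homozygous cells. It was not called in any of the 3 comparisons (adjusted p = 0.588, 0.158 and 0.264 for homozygous against wild type, heterozygous against wild type and homozygous against heterozygous). Homozygous replicate 3 held the lowest levels of the 9 libraries for POU5F1 (33.5 CPM), NANOG (1.45 CPM) and SOX2 (0.848 CPM). The mean log2 level of the 25 pluripotency genes relative to the wild-type mean was 0.16, -0.05 and -0.11 in the wild-type replicates, 0.50, 0.48 and 0.09 in the heterozygous replicates, and 0.13, 0.01 and -0.49 in the homozygous replicates. In homozygous against wild-type cells NANOG had a log2 fold change of -1.30 (SE 0.37, adjusted p = 0.0547) and SOX2 of -0.16 (SE 0.56, adjusted p = 0.892). Of the 25 list members, 2 fell and none rose in that comparison (0 rose and 3 fell adjusted over the list alone), and the list was not called (camera, adjusted p = 0.344).

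**Figure D2:**
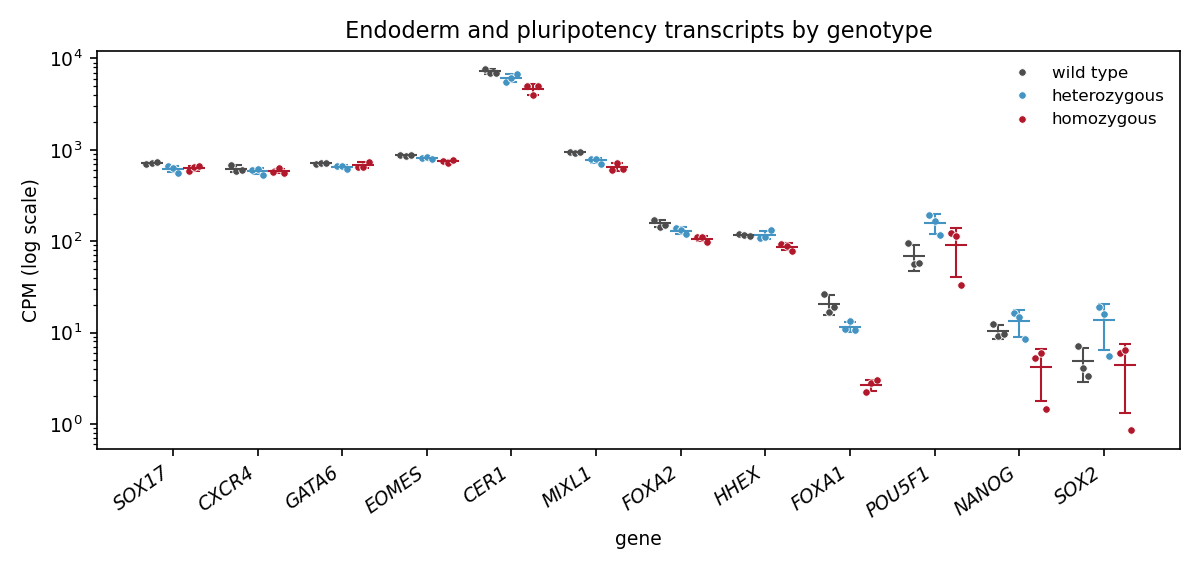
Levels in CPM (vertical axis, log scale) of 12 endoderm and pluripotency genes (horizontal axis) by genotype, with 1 point per library, horizontal bars for the means and error bars for the SD of 3 libraries. FOXA1 falls to 2.68 CPM in homozygous cells while SOX17, CXCR4, GATA6 and EOMES stay at or above 537 CPM in every library, and POU5F1, NANOG and SOX2 are lowest in homozygous replicate 3.

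Markers of other lineages changed in small numbers in homozygous cells. The trophoblast and amnion list was called upwards, with 2 of its 6 tested members rising and none falling (3 rose and 1 fell adjusted over the list alone; camera, adjusted p = 0.0493; adjusted p = 0.493 with an estimated correlation). The risers were GATA3, a trophectoderm transcription factor (log2 fold change 1.36, SE 0.22, adjusted p = 0.00233), and TFAP2C, its partner in that lineage (1.23, SE 0.15, adjusted p = 0.000216). The list score was 0.84 in homozygous replicate 3 against 0.01 and 0.26 in homozygous replicates 1 and 2, and the list call was lost without homozygous replicate 3 (adjusted p = 0.262), wild-type replicate 1 (0.0878) or wild-type replicate 3 (0.0518). With the replicate number as a block, no list was called upwards in this comparison. In the primitive and visceral endoderm list 3 of 18 rose and 1 fell (3 and 3 adjusted over the list alone), among them HNF4A, a nuclear receptor of liver and visceral endoderm (0.77, SE 0.11, adjusted p = 0.000873). In the foregut, liver and pancreas list 2 of 11 rose and 1 fell (3 and 1 adjusted over the list alone). Its faller was NKX6-1, a pancreatic transcription factor at 2.41 ± 0.512 CPM in wild-type and 0.116 ± 0.135 CPM in homozygous cells (adjusted p = 0.00180), while the motor neuron and pancreas gene MNX1 rose from 3.79 ± 1.05 to 8.92 ± 1.91 CPM (adjusted p = 0.00513). In the mesoderm list 2 of 17 rose and 1 fell (2 and 2 adjusted over the list alone), the faller being KDR, a VEGF receptor (-1.05, SE 0.19, adjusted p = 0.00419). The primitive streak list had 0 rising and 1 falling of 14 (0 and 3 adjusted over the list alone), the neuroectoderm list 1 and 0 of 19 (2 and 2) and the neural crest list 0 and 2 of 16 (0 and 2). None of these lists other than trophoblast and amnion was called (camera, adjusted p from 0.160 to 0.763), and for the foregut list the median was positive and the mean negative, with the test pointing up. Tested against a 1.5-fold change, KDR, HNF4A and MNX1 were no longer called (adjusted p = 0.151, 0.422 and 0.0831).

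In homozygous cells more members fell than rose in the Nodal and Activin, axon guidance, hypogonadism and hypoxia lists, a difference not tested as such. The Nodal and Activin target list was called downwards, with 5 of 19 members falling and none rising (7 fell and 1 rose adjusted over the list alone; camera, adjusted p = 0.0493; adjusted p = 0.326 with an estimated correlation). Its falling members included CER1 and MIXL1. The axon guidance list was called downwards with 10 of 40 members falling and 2 rising (14 and 7 adjusted over the list alone; camera, adjusted p = 0.0493; adjusted p = 0.524 with an estimated correlation). Members that fell included the neuropilin NRP1 (log2 fold change -1.66, SE 0.22), the netrin receptor UNC5C (-1.46, SE 0.17) and the semaphorin SEMA3D (-1.99, SE 0.25). The list of genes linked to hypogonadotropic hypogonadism and CHARGE syndrome was called downwards, with 5 of 22 falling and 1 rising (6 and 2 adjusted over the list alone; camera, adjusted p = 0.0493; adjusted p = 0.326 with an estimated correlation). They included ANOS1, the X-linked Kallmann syndrome gene (-0.97, SE 0.15, adjusted p = 0.00133), and the adhesion receptor FLRT3 (-1.31, SE 0.13, adjusted p = 5.30e-05). The hypoxia and glycolysis list was called downwards with 3 of 24 falling and 1 rising (4 and 1 adjusted over the list alone; camera, adjusted p = 0.0429; adjusted p = 0.326 with an estimated correlation), led by the vasodilator peptide gene ADM (-1.30, SE 0.12) and the kinase gene PDK1 (-1.21, SE 0.11). With the replicate number as a block, only 1 list was called downwards in homozygous against wild-type cells. Without wild-type replicate 1 the calls of all 4 lists were lost (adjusted p = 0.0932 for Nodal, 0.0810 for axon guidance, 0.0810 for hypogonadism and 0.0682 for hypoxia). The Nodal call was also lost without homozygous replicate 1 (0.0646), the axon guidance call without homozygous replicate 2 (0.160) or heterozygous replicate 3 (0.0518), and the hypogonadism call without homozygous replicates 1 (0.0610) or 2 (0.0508). Fry did not call the axon guidance list (adjusted p = 0.0824) but called the Nodal, hypogonadism and hypoxia lists. ANOS1 was not called against a 1.5-fold change (adjusted p = 0.114).

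The remaining lists were not called in homozygous against wild-type cells (camera, adjusted p from 0.0620 to 0.911). In the extracellular matrix list 3 of 34 rose and 6 fell (5 and 8 adjusted over the list alone), with the matrix glycoprotein TNC going from 390.2 ± 9.62 to 143 ± 9.87 CPM (log2 fold change -1.44, SE 0.11, adjusted p = 5.30e-06). In the epithelial to mesenchymal transition list 5 of 23 fell (7 fell and 1 rose adjusted over the list alone), including the collagen crosslinking enzyme LOX (-3.07, SE 0.25) and COL1A2 (-0.89, SE 0.14). The Wnt list had 2 risers and 4 fallers of 27 (2 and 4 adjusted over the list alone), with the Wnt inhibitor DKK4 at -2.67 (SE 0.36, adjusted p = 0.000570). The BMP list had 3 risers and 2 fallers of 18 (3 and 2), among them the inhibitory SMAD6 (0.61, SE 0.11). SMAD6 and COL1A2 were not called against a 1.5-fold change (adjusted p = 1 and 0.213). Median and mean differed in sign for the epithelial to mesenchymal, Wnt and culture-variable lists, with the test following the mean, and in the BMP list the test pointed up while both were negative. In the list of genes known to vary between stem cell cultures, 3 of 13 rose and 2 fell (4 and 3), the fallers being ZNF562 and TSPYL5. The other lists, given as rising and falling members with those adjusted over the list alone in parentheses, were imprinted genes with 2 and 2 of 21 (3 and 2), p53 targets with 1 and 2 of 29 (1 and 3) and the CHD family with 1 and 0 of 9 (1 and 0). BAF and PBAF subunits had 0 and 2 of 26 (0 and 2), the stress and unfolded protein response list 0 and 2 of 21 (0 and 2) and heat shock and immediate early genes 0 and 2 of 18 (1 and 3). Proliferation genes (29 tested), mitochondrially encoded genes (13) and the 20q11.21 amplicon (14) had 0 called members, also adjusted over the list alone. Of the 39 HOX genes 1 had a row in the table and 0 were tested.

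**Figure D3:**
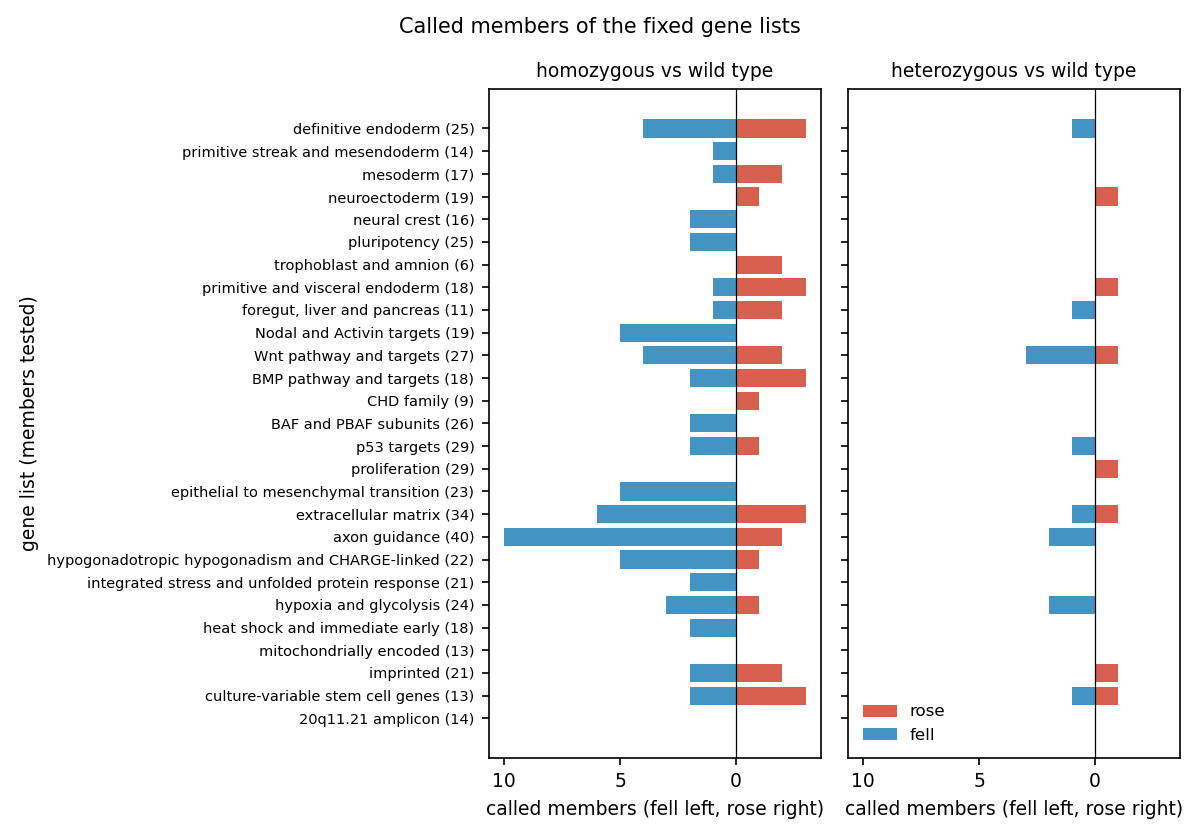
Number of called members (horizontal axis, falling to the left and rising to the right) of the 27 gene lists with tested members (vertical axis, members tested in parentheses) in homozygous and in heterozygous against wild-type cells. The axon guidance bar in homozygous cells is the longest, with 10 falling and 2 rising members, and no list in heterozygous cells has more than 3 falling members.

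Large changes in homozygous cells were found both in and outside these lists. The antisense transcript NECTIN3-AS1 (chromosome 3, 110893708 to 111071553, minus strand) rose from 0.257 ± 0.120 to 48.2 ± 2.85 CPM (log2 fold change 7.61, SE 0.20, adjusted p = 3.59e-10). Its sense partner NECTIN3 was not called (-0.40, SE 0.16, adjusted p = 0.139). The divergent transcript YPEL3-DT rose by 4.92 (SE 0.17), and its neighbour YPEL3 also rose (1.18, SE 0.12, adjusted p = 6.79e-05). Whether the counting used strand is not given in the sources used here, so overlapping and antisense pairs cannot be separated with certainty. GRPR, the gastrin-releasing peptide receptor gene on the X chromosome (16123556 to 16153021, plus strand), rose from 2.61 ± 0.792 to 33.9 ± 5.04 CPM (3.67, SE 0.20, adjusted p = 2.63e-07). Other large rises were those of ZNF469 (6.74, SE 0.46), the calcium-binding protein gene S100A6 (4.33, SE 0.37) and the LIM domain gene CSRP1 (4.34, SE 0.43). The zinc-finger gene ZNF626 (chromosome 19, 20620061 to 20661596, minus strand) had 772 counts in the wild-type libraries and 0 in the homozygous libraries, at least 174.3-fold lower when the floor is set at 3 counts over the genotype. In the culture-variable list, the zinc-finger gene ZNF562 stood at 15.0 ± 0.918 and 0.0552 ± 0.0956 CPM, and TSPYL5 had 200 counts in wild-type and 0 in homozygous libraries, at least 45.2-fold lower. The kinase gene MAP3K13 fell from 12.5 ± 0.861 to 0.410 ± 0.210 CPM (-4.88, SE 0.24, adjusted p = 1.59e-07). Zinc-finger genes have close paralogs that can share reads.

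Of 16837 genes tested, 1293 were called in homozygous against wild-type cells, 589 up and 704 down. The excess of falls turned with upper quartile scaling (712 up and 607 down) and without wild-type replicate 1 (500 up and 486 down). At an unadjusted p below 0.05 there were 3906. The count was 651 without wild-type replicate 2, 700 without wild-type replicate 3 and 2118 without homozygous replicate 3, and 281 genes were called against a 1.5-fold change.

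In heterozygous cells fewer genes were called, and core endoderm transcripts remained abundant. FOXA1 was the single called member of the 25 definitive endoderm genes (log2 fold change -0.83, SE 0.17, adjusted p = 0.0266), with 1 rising and 2 falling adjusted over the list alone. That call was lost without wild-type replicates 1 (adjusted p = 0.0677) or 3 (0.0688) and without heterozygous replicates 1 (0.113), 2 (0.0597) or 3 (0.0750). SOX17 (-0.21, SE 0.08, adjusted p = 0.279), CER1 (-0.24, SE 0.11, adjusted p = 0.346) and MIXL1 (-0.30, SE 0.09, adjusted p = 0.125) did not pass the test. NKX6-1 was at 0.0828 ± 0.113 CPM (-4.92, SE 0.67, adjusted p = 0.00146), the 1 falling member of the foregut list (0 and 1 of 11, also adjusted over the list alone). In the hypoxia list ADM fell (-0.68, SE 0.12, adjusted p = 0.00884), and so did PDK1 (-0.59, SE 0.11, adjusted p = 0.0112), a call lost without wild-type replicate 2 (0.0553). In the Wnt list 3 of 27 fell and 1 rose, and its faller DKK4 (-1.84, SE 0.33, adjusted p = 0.0110) lost its call without wild-type replicates 2 (0.0637) or 3 (0.0530) or heterozygous replicate 2 (0.0982). Against a 1.5-fold change FOXA1, ADM, PDK1 and DKK4 were not called (adjusted p = 1, 1, 1 and 0.0683). The proliferation list was the 1 called list of 27, upwards (camera, adjusted p = 0.00132; adjusted p = 0.756 with an estimated correlation). It had 1 called member of 29 and 7 rising adjusted over the list alone, and its call was lost without heterozygous replicates 1 (adjusted p = 0.0962) or 2 (0.0763). Those libraries also had the highest pluripotency scores, 0.50 and 0.48. The pluripotency list had 0 called members of 25, with 4 rising adjusted over the list alone (camera, adjusted p = 0.0926).

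The other lists in heterozygous cells had 2 or fewer called members each. Axon guidance had 0 rising and 2 falling of 40 (4 and 9 adjusted over the list alone), the matrix list 1 and 1 of 34 (3 and 4), the culture-variable list 1 and 1 of 13 (4 and 2) and the hypoxia list 0 and 2 of 24 (0 and 3). The p53 list had 0 and 1 of 29 (0 and 1), the primitive and visceral endoderm list 1 and 0 of 18 (2 and 1), neuroectoderm 1 and 0 of 19 (1 and 2) and imprinted genes 1 and 0 of 21 (1 and 0). Among the lists with 0 called members, the epithelial to mesenchymal list had 6 rising and 3 falling adjusted over the list alone, Nodal and Activin targets 0 and 3, the BMP list 1 and 2, heat shock and immediate early genes 0 and 2, neural crest 0 and 1 and the hypogonadism list 0 and 1. Adjusted over the list alone the Wnt list had 1 rising and 3 falling. Mesoderm, primitive streak, trophoblast, CHD family, BAF, stress, mitochondrial and 20q11.21 lists had 0 on either count. None of these was called (camera, adjusted p from 0.0926 to 0.999). Median and mean differed in sign for the definitive endoderm, primitive streak and 20q11.21 lists, with the test following the median, and for the culture-variable list, with the test pointing up and the mean negative. For the neuroectoderm, neural crest and stress lists both were positive and the test pointed down. Large changes were again found in and outside the lists. TSPYL5 of the culture-variable list had 200 counts in wild-type and 0 in heterozygous libraries, at least 59.3-fold lower. NHIP, with 0.115 ± 0.0779 CPM in wild-type cells, stood at 7.39 ± 2.41 CPM (5.89, SE 0.39, adjusted p = 4.46e-06), and NECTIN3-AS1 at 6.13 CPM (4.64, SE 0.22, adjusted p = 2.24e-07). ECHDC3 (4.54, SE 0.31), BEX5 (3.32, SE 0.26) and the clustered protocadherin PCDHA11 (3.59, SE 0.26), whose exons overlap those of its neighbours, also rose. PNPLA4, a lipase gene of the X chromosome, fell from 14.8 ± 0.933 to 1.13 ± 0.160 CPM (-3.70, SE 0.23, adjusted p = 2.14e-06). ZNF826P, a zinc-finger pseudogene on chromosome 19 (20340269 to 20424969, minus strand), had 3366 counts in wild-type and 0 in heterozygous libraries, at least 997.7-fold lower. ZNF677, on the same chromosome (53235381 to 53254898, minus strand), had 831 and 0 counts, at least 246.3-fold lower.

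In heterozygous against wild-type cells 313 genes were called, 138 up and 175 down, and 2274 had an unadjusted p below 0.05. The excess of falls turned with DESeq2 (284 up and 276 down), without all replicates numbered 3 (181 up and 179 down) and without wild-type replicate 1 (201 up and 158 down). DESeq2 called 560, the fit of the 6 libraries alone 604 and the test against a 1.5-fold change 89. The count was 135 without wild-type replicate 2, 130 without wild-type replicate 3, 173 and 147 without heterozygous replicates 1 and 2, and 624 without homozygous replicate 3.

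The mutant genotypes were then compared with each other. FOXA1 was lower in homozygous than in heterozygous cells (log2 fold change -2.10, SE 0.20, adjusted p = 7.73e-05), as were TNC (-0.94, SE 0.11, adjusted p = 0.000344), the stress-response factor ATF3 (-0.91, SE 0.13, adjusted p = 0.00252), FLRT3 (-0.80, SE 0.13, adjusted p = 0.00592) and LOX (-2.38, SE 0.26). GATA3 (1.42, SE 0.23, adjusted p = 0.00553), HNF4A (0.83, SE 0.11, adjusted p = 0.00144) and FRZB (0.69, SE 0.11, adjusted p = 0.00553) were higher. Of these, FOXA1 and LOX were still called against a 1.5-fold change. Of the 27 lists 5 were called downwards and 2 upwards, and 0 of the 7 kept their call with an estimated correlation (lowest adjusted p = 0.138). The pluripotency list was called downwards (camera, adjusted p = 0.00136; adjusted p = 0.352 with an estimated correlation), with 2 of 25 falling and 10 falling and 2 rising adjusted over the list alone. NANOG was among them (-1.65, SE 0.37, adjusted p = 0.0401), a call lost without any 1 of wild-type replicates 1 (0.0509), 2 (0.0631) or 3 (0.0659), heterozygous replicates 1 (0.0876) or 2 (0.139), or homozygous replicate 1 (0.0699). The list of culture-variable genes (adjusted p = 0.00134; adjusted p = 0.138 with an estimated correlation) had 1 of 13 falling, ZNF562, with 4 falling and 2 rising adjusted over the list alone. The epithelial to mesenchymal list had 2 of 23 falling (adjusted p = 0.00784; adjusted p = 0.352 with an estimated correlation), the stress and unfolded protein response list 2 of 21 (adjusted p = 0.0310; adjusted p = 0.583 with an estimated correlation) and the mitochondrially encoded list 0 of 13 (adjusted p = 0.0310; adjusted p = 0.583 with an estimated correlation). The upward lists were trophoblast and amnion, with 2 of 6 rising (adjusted p = 0.00451; adjusted p = 0.352 with an estimated correlation), and foregut, liver and pancreas, with 2 of 11 (adjusted p = 0.0353; adjusted p = 0.352 with an estimated correlation). Without homozygous replicate 3 the epithelial to mesenchymal (adjusted p = 0.110), stress (0.107), mitochondrial (0.120), trophoblast (0.120) and foregut (0.107) calls were lost. The stress call was also lost without heterozygous replicate 3 (0.287) or homozygous replicate 1 (0.0811), the mitochondrial call without heterozygous replicates 1 (0.0730) or 3 (0.174) or homozygous replicate 2 (0.0720), and the foregut call without heterozygous replicate 1 (0.103) or homozygous replicate 2 (0.0812). Adjusted over the list alone, the epithelial to mesenchymal list had 0 rising and 3 falling, the stress list 0 and 2, the mitochondrial list 0 and 0, the trophoblast list 3 and 0 and the foregut list 2 and 1.

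The other 20 lists were not called between the mutants (camera, adjusted p from 0.149 to 0.870). Rising and falling members, with those adjusted over the list alone in parentheses, were 1 and 2 of 25 for definitive endoderm (2 and 5), 1 and 3 of 40 for axon guidance (1 and 5), 0 and 3 of 22 for the hypogonadism list (1 and 5) and 2 and 0 of 18 for BMP (2 and 1). They were 0 and 2 of 24 for hypoxia (0 and 2), 1 and 1 of 27 for Wnt (1 and 2), 1 and 1 of 34 for matrix (1 and 3), 0 and 1 of 18 for heat shock (0 and 2), 1 and 0 of 18 for primitive and visceral endoderm (1 and 0) and 0 and 1 of 16 for neural crest (0 and 1). The Nodal (1 and 2 adjusted over the list alone), neuroectoderm (1 and 1), p53 (2 and 2) and imprinted (2 and 1) lists had 0 called members. The primitive streak, mesoderm, CHD family, BAF, proliferation and 20q11.21 lists had 0 on either count. Medians were positive and means negative, with the test pointing down, for the definitive endoderm, Wnt, matrix and hypogonadism lists. For the BMP and 20q11.21 lists both were negative and the test pointed up.

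Between the mutants 372 genes were called, 166 higher and 206 lower in homozygous cells, and 3077 had an unadjusted p below 0.05. DESeq2 called 819, the fit of the 6 libraries alone 177 and the test against a 1.5-fold change 67. The excess of falls turned in that fit (103 up and 74 down), in that test (39 up and 28 down), with upper quartile scaling (50.3% of the calls up) and without heterozygous replicate 2 (74 up and 67 down) or homozygous replicate 2 (120 up and 91 down), and it was gone without wild-type replicate 2 (114 up and 114 down). The count was 228 and 238 without wild-type replicates 2 and 3, 242 and 141 without heterozygous replicates 1 and 2, and 211 without homozygous replicate 2.

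Changes in both mutants against wild type overlapped. Of the 313 genes called in heterozygous cells, 239 (76.4%) were called in the same direction in homozygous cells, 101 up and 138 down, and 5 were called in opposite directions. Genes shared in direction included NECTIN3-AS1, YPEL3-DT, GRPR, BEX5, NHIP, PNPLA4 and ADM. Independent lists of these sizes would share 4.83 rising and 7.32 falling genes. In 100 simulated sets of unchanged groups sharing the 3 wild-type libraries, at most 1 gene was shared. Sets of this kind call almost no genes, on average 0.15 in homozygous against wild-type cells. Their shared count is therefore near 0 by construction and is no yardstick for the 239. Unrelated real changes in both mutants were not simulated. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.597, against a mean of 0.473 and a maximum of 0.496 in the simulated sets. The covariance was 0.177 against a simulated 0.0309, a difference of 0.146. The 3 wild-type libraries cannot be split into groups of at least 2 libraries, so part of the excess may come from the shared controls. The shared count was 103 and 101 without wild-type replicates 2 and 3, 141 and 119 without heterozygous replicates 1 and 2, and 476 without homozygous replicate 3.

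**Figure D4:**
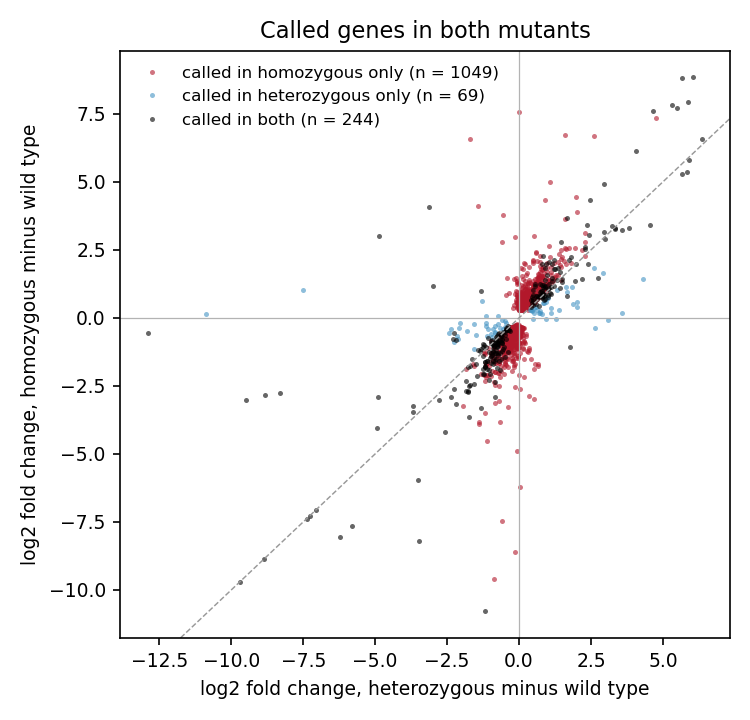
Log2 fold change against wild type in heterozygous cells (horizontal axis) and homozygous cells (vertical axis) of the 1362 genes called in either, 1 point per gene, with a dashed line of equal change. Of the points 1049 were called in homozygous cells only, 69 in heterozygous cells only and 244 in both, and fitted values of genes without counts in a genotype depend on the prior count.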

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

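For the genes on in 1 genotype and off in another, the tests of the CHD7 order, of the state of the cell line and of shared reads were chosen only after the result was seen. Against wild type, 9 named genes changed in heterozygous cells and then turned back or went beyond in homozygous cells, by edgeR's test between the mutants with Benjamini-Hochberg adjustment. The zinc-finger pseudogene ZNF826P and the zinc-finger gene ZNF677 had 0 counts in heterozygous cells, at least 642.3-fold and 258.1-fold lower than in homozygous cells. Their fitted log2 fold changes of homozygous minus heterozygous cells, 12.33 and 11.02, depend on the prior count. LRRC61 had 2 counts in heterozygous cells and 434 in homozygous cells, a ratio of 284.8 (95% counting interval 78.4 to 2359) and a fitted log2 fold change of 7.86. ZBED10P had 3 and 368 counts, a ratio of 161 (54.7 to 784) and a fitted log2 fold change of 7.20. Its fall in heterozygous against wild-type cells (adjusted p = 0.0376) was not called without wild-type replicates 1 (0.0858) or 3 (0.145), heterozygous replicates 1 (0.0775), 2 (0.163) or 3 (0.0880), or homozygous replicate 1 (0.0532). The clustered protocadherin PCDHA10 had a log2 fold change between the mutants of 1.87 (adjusted p = 0.000103), ZNF737 of 1.49 (adjusted p = 0.000306), ZNF69 of 1.70 (adjusted p = 5.96e-05) and TSPEAR-AS1 of 1.69 (adjusted p = 9.25e-05). ECHDC3 was lower in homozygous than in heterozygous cells, with a log2 fold change of -1.14 (adjusted p = 0.0329), and was not called without wild-type replicate 2 (0.0523), heterozygous replicates 1 (0.0830) or 2 (0.139), or homozygous replicates 2 (0.0979) or 3 (0.0635). Groups of 3 libraries were not tested for outlying libraries.

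In all, 33 genes were on in 1 genotype and off in another, at a minimum of 2 CPM in the highest genotype and 16-fold above the lowest, limits set after the data were seen. No level was set for off, so graded changes are included, such as YPEL3-DT with 1.28 CPM in wild-type cells. Heterozygous cells stood apart in 6 of the 33 genes, homozygous cells in 11 and wild-type cells in 16. Reads shared through identical sequence are argued against for these genes as a set, but not for each gene. The lower quartile of the share of 51-mers found in no other gene was 92.6% over the 27 genes with a value. PCDHA6 was lowest at 40.9%, and TRIM61 stood at 69.0%. Only exact matches in annotated transcripts were counted, so reads placed with mismatches or from unannotated copies are not covered. An order by CHD7 copy number is argued against for 6 of the 33 (LRRC61, TRIM61, ZNF677, ZNF680, ZNF772 and ZNF826P). Their heterozygous means lay below those of both other genotypes, and they were called in opposite directions in both steps whichever library was left out. The 6 were picked by these same calls, so the statement covers them alone and is no test of the 33 as a set. As a rough yardstick, 100 simulated sets with heterozygous cells midway gave at most 4 opposite calls over all genes. Leave-one-out fits were not run on those sets. In fits of the 6 libraries of each comparison alone, 5 of the 9 on/off genes called in opposite directions kept both calls. Not all of the 6 therefore kept them there. The order by copy number stays open for 3 (ZBED10P, ECHDC3 and PCDHA6), whose opposite calls are lost without some libraries, and for the other 24, of which 7 were called in both steps in 1 direction. A state of the cell line unrelated to CHD7, such as a difference between clones, may also be the source and stays open. Heterozygous cells stood apart in 18.18% of the genes (95% exact interval 6.98 to 35.5%, two-sided exact binomial p = 0.0669 against 33.3%). Among the 1227 other called genes with at least 2 CPM in the highest genotype they did so in 4.73% (odds ratio 4.47, two-sided Fisher's exact p = 0.00509). Neither test can decide, since such a state need not set each genotype apart equally often and the genes are not independent.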

How the results depend on the processing

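The pluripotency covariate, thinning, the omission of all replicates numbered 3 and the removal of the GC trend were chosen only after the result was seen. No named gene, list or CHD7 call reversed its direction, but the excess of falling over rising genes turned under some alternatives. In homozygous against wild-type cells it turned with upper quartile scaling (712 up and 607 down), in heterozygous cells with DESeq2 (284 and 276) and the block (264 and 228), and between the mutants with the 6 libraries alone (103 and 74), against a 1.5-fold change (39 and 28) and with upper quartile scaling (50.3% of the calls up). Counting each call of a named gene other than CHD7 once per fit, 1248 stayed and 237 were lost when 1 library was left out. Under the other alternatives 1954 stayed and 190 were lost. Kept in every leave-one-out fit were 62 of 86 named genes called in homozygous against wild-type cells. In heterozygous against wild-type cells 23 of 40 were kept, and between the mutants 31 of 42. Of the list calls, also counted once per fit, 91 stayed and 26 were lost when 1 library was left out, and 27 stayed and 25 were lost under the others. The number of genes called in homozygous against wild-type cells was 281 against a 1.5-fold change and 2902 with the covariate, and 651 to 2118 when 1 library was left out. In heterozygous against wild-type cells it was 560 with DESeq2, 604 with the 6 libraries alone, 492 with the replicate block, 89 against a 1.5-fold change and 174 with the covariate, and 130 to 624 when 1 library was left out. In homozygous against heterozygous cells it was 819 with DESeq2, 177 with the 6 libraries alone, 67 against a 1.5-fold change and 1175 with the covariate, and 141 to 377 when 1 library was left out. CHD7 in heterozygous cells kept its log2 fold change of -0.65 and was not called against a 1.5-fold change, a stricter null by construction. The lists called in homozygous against wild-type cells were 0 with an estimated correlation, 8 with fry and 1 with the block (0 to 9 when 1 library was left out). Those in heterozygous cells were 0, 2 and 2 (0 to 3), and those between the mutants were 0 with an estimated correlation, 5 with fry and 6 with the block (2 to 10). The shared calls of both mutants were 387 with DESeq2 and 101 to 476 when 1 library was left out. For the other changes the cause was not tested. The replicate numbers are neither shown to pair the libraries nor excluded from doing so. The 9 same-number pairs had residual correlations from -0.195 to 0.245, 4 of them above 0.1. The 18 other pairs ranged from -0.433 to 0.358. For 1 library its own number was the best match in both other genotypes. The shallowest library held 11854173 counts, and at that depth for all libraries 1068, 232 and 268 genes were called.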

Other observations

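The zinc-finger share, the fits with the pluripotency score as a covariate, the tests of depth, GC content, undifferentiated cells and clones on the number of calls, and the simulated orders of the genotypes were chosen only after the result was seen. Of the 1293 genes called in homozygous against wild-type cells, the heterozygous fold change lay between 0 and the homozygous one in 1106 (85.5%), with a median ratio of 0.446. Part of this is built in by the choice of genes and the shared wild-type libraries: in 100 simulated sets the share averaged 64.4% and the ratio 0.0886 with heterozygous cells like wild type, and 94.5% and 0.497 with heterozygous cells midway. Against this order, and including the 9 named ones, 39 genes were called in opposite directions from wild-type to heterozygous and from heterozygous to homozygous cells, 26 of them lower and 13 higher in heterozygous cells. The simulated sets gave at most 2 such genes with heterozygous cells like wild type and at most 4 with heterozygous cells midway. These sets called on average 2770 and 2778 genes in homozygous against wild-type cells, more than the 1293 of the data. Their shares, ratios and counts are therefore only a rough yardstick. Of the 39 genes, 23 kept both calls whichever library was left out, and the count of such genes was 25 without wild-type replicate 2, 23 without heterozygous replicate 2, 63 with DESeq2 and 19 against a 1.5-fold change. Zinc-finger genes made up 8 of the 33 genes that were on in 1 genotype and off in another (24.2%), against 3.77% of the 12852 genes that had the level to qualify (odds ratio 8.28, 95% interval 3.21 to 19.1, two-sided Fisher's exact p = 2.34e-05). The test treats genes as independent, although several of the 8, such as ZNF677, ZNF826P and ZNF626, lie on chromosome 19. Its p-value and interval may therefore overstate the evidence. Median log2 fold changes by chromosome lay between -0.13 and 0.09 in the 3 comparisons.

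More genes were called in homozygous than in heterozygous cells against wild type, 1293 against 313, a ratio of 4.13, which was 1.95 with the 6 libraries of each comparison alone, 16.7 with the pluripotency covariate, 2.75 without wild-type replicate 1, 2.13 without homozygous replicate 2, and 7.13 and 7.09 without heterozygous replicates 1 and 2. Library depth and GC content are argued against as the whole cause, since the ratio was 4.60 after thinning all libraries to 1 total count and 3.52 with the GC trend of each library removed. With the pluripotency score as a covariate 100% of the homozygous calls stayed, with a median ratio of the fold changes of 1.04 (quartiles 0.983 to 1.09). The mean score differed little between homozygous and wild-type cells, so the covariate could hardly remove these calls. Of the 313 heterozygous calls 148 stayed. In all, 2902 genes were then called in homozygous and 174 in heterozygous cells, and the ratio of calls rose to 16.7. The excess of homozygous calls was thus larger with the score held equal. This argues against a differing share of undifferentiated cells as its source, as far as this score measures that share. A clonal difference between lines stays open beside the number of deleted copies, since 0 labels name a clone. Of the 10 splits of the 6 libraries in each comparison, 1 called as many genes as the real one, the real one itself, with 1293, 313 and 372 genes against at most 96, 1 and 0 in the others, and 10 splits are too few for a share under 0.05.

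The pluripotency genes spread between libraries of 1 genotype, with POU5F1 from 33.5 to 122 CPM in homozygous cells. Library depth is argued against, since the spread of the score kept 89.7% of its value after thinning. Undifferentiated cells carried over into some libraries are a candidate explanation. The 25 genes, all of them expressed in these endoderm libraries above the filter, deviated together with a median correlation of 0.1528. This lay above the 95th percentile of 0.104 of random lists (168 of 10000 as high). The random lists matched the genes in number and expression level only. Any genes regulated together could exceed them, so the test does not single out carried-over cells. With the score as a covariate, 148 of the 313 heterozygous calls stayed, the median ratio of the fold changes was 0.916 (quartiles 0.763 to 1.03) and the median SE went from 0.177 to 0.191. No explanation of this spread other than depth and carried-over cells was tested.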
